A study of Caenorhabditis elegans with 6 samples.

How the data were processed

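The 6 libraries of total RNA from whole C. elegans N2 comprised 3 from worms fed control L4440 bacteria and 3 from worms fed vit-5 RNAi bacteria, grouped by their titles. Per the labels' protocols, RNA was extracted with Trizol from worms settled in M9 buffer, and libraries were made with the NEBNext Ultra RNA kit and sequenced on an Illumina NovaSeq. Selection of polyadenylated RNA and strandedness are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, TopHat without a version, HTSeq 0.6.1, DESeq 1.18.0 and the genome build WBcel235, without saying what each did. The authors deposited 1 FPKM value per gene and library, per the file headers. The program that computed the FPKM is not given in the sources used here. Most zeros were written as 0.0001, and 4 to 15 values per library lay below that.

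Each library lists the same 45132 NCBI gene IDs. Symbols, biotypes and coordinates were taken by gene ID from a RefSeq gene table of WBcel235, in which 45010 IDs matched, and 1217 of them had a current symbol that differed from the name beside the values. The mitochondrially encoded genes, under the names written in their list, had 0 matches and were not analysed here. No read counts were in the files used here. FPKM times transcript length clustered near steps of 1 fragment for low genes, which gave the rough depths, from 17300000 fragments (vit-5 RNAi replicate 2) to 21600000 (control replicate 1). Only 30.9% to 33.6% of low values lay within 0.1 of a whole fragment, where chance gives 20%, so counts could not be recovered and no counting interval is given.

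The design written before the data were examined assumed counts first and named limma for the case of FPKM, and that branch was used. Values were transformed as log2(FPKM + 1), so fold changes of genes at low FPKM are understated. Genes with at least 1 FPKM in at least 3 libraries were kept, 12908 in all, of which 12497 are protein-coding. The fit in limma 3.58.1 under R 4.3.3 had the group as its only term, with a mean-variance trend, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Fold changes are vit-5 RNAi minus control. Tests were 2-sided. Single values were compared by exact permutation, which with 3 against 3 cannot give a p under 0.1.

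A set of 30 gene lists was written from general knowledge of worm biology before the data were examined, and the 29 with at least 3 tested genes were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists. None of the 29 lists kept a call with an estimated correlation, the smallest adjusted p then being 0.702. The fry test, which asks whether a list's genes move on balance one way without comparing them with other genes, gave a smallest adjusted p of 0.0791 over the lists. Its mixed version, which counts changes either way, passed for 11 of the 29 lists, with adjusted p-values from 0.0136 to 0.0474. Members were also adjusted over the list alone, which does not correct for the number of lists tested. The rule for named genes took vit-1 to vit-6 and, since fewer than 10 genes passed, the 10 with the smallest p, of which 3 are vitellogenins. Other members of lists, and Y48G8AL.17 and C09H10.19, were named after their values were seen, and most list members are those that passed over the list alone.

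The procedure was tested on simulated data for the same comparison of 3 libraries against 3 with 12908 genes, each with its own residual SD. It recovered 30% of 50 genes changed by a log2 size of 1, 76% at 2, 92% at 3 and 98% at 5, and called 11 of 12708 unchanged genes. The changed genes were drawn from those with a control mean log2 value above 3. All changes of size 3 and 5 were upward, and the noise was independent between genes. These shares therefore do not cover genes at low FPKM, large falls such as that of vit-5, or genes that vary together. Replicates were compared before they were averaged, and Pearson's r of the log2 values was 0.927 to 0.989 within groups and 0.928 to 0.984 between groups. No 2 libraries were copies of each other, since at most 0.0697% of tested genes had exactly equal values in any pair. Alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values, the replicate number as a block, leaving out each library and an estimated correlation in camera. Added after the data were seen were median-of-ratios, upper-quartile and quantile scaling, taking vitellogenin and ribosomal RNA genes out of the FPKM sum, ribosomal RNA or molting gene level as a covariate, leaving out the library richest in ribosomal RNA of each group, and protein-coding genes only. Figures were drawn with matplotlib 3.10.9, and tables were read in Python 3.11.15.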

Results

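RNA was sequenced from whole wild-type Caenorhabditis elegans (strain N2) fed bacteria that silence vit-5, a gene for a yolk protein, or bacteria carrying the empty L4440 vector as the control. Feeding with the RNA interference (RNAi) bacteria took place in larvae, young adults were moved to OP50 bacteria, and worms were collected as 5-day-old animals. There were 3 control RNAi and 3 vit-5 RNAi libraries, each with 1 FPKM value (fragments per kilobase of transcript, scaled to library size) for 45132 genes. Depth is not stated in the sources used here. The spacing of the lowest values gave rough estimates of 17300000 to 21600000 fragments per library. Libraries listed 12250 ± 199 genes (SD, n = 3) at or above 1 FPKM in the control group and 13136 ± 319 (SD, n = 3) in the vit-5 RNAi group. These ranges did not overlap, and the exact 2-sided permutation p was 0.1, the smallest that 3 libraries against 3 can give. The labels do not say whether replicates came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

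The first question was whether vit-5 RNAi lowered its target. Vitellogenins are yolk proteins made in the adult intestine and taken up by oocytes. The transcript of vit-5 (gene ID 180630; WBcel235, chromosome X, 3403471 to 3408603) stood at 1768 ± 499 FPKM (SD, n = 3) in control worms and 63.4 ± 47.6 (SD, n = 3) after vit-5 RNAi, a 27.9-fold ratio of means. The control libraries held 2335, 1396 and 1573 FPKM and the vit-5 RNAi libraries 116, 51.6 and 22.8 FPKM. Its close copies showed as large a difference. For vit-4 (X, 3558769 to 3563965) the means were 828 ± 377 and 23.8 ± 20.96 FPKM, and for vit-3 (X, 3567355 to 3572549) they were 691 ± 272 and 32.3 ± 28.6 FPKM (SD, n = 3 each). All 3 genes fell when p-values were adjusted over the list alone, the 6 vitellogenins. The log2 fold changes of log2(FPKM + 1) were -5.03 (SE 0.50) for vit-5, -5.48 (SE 0.72) for vit-4 and -4.83 (SE 0.71) for vit-3, with list-alone adjusted p of 4.08e-05, 0.00016 and 0.000246 by limma.

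Adjusted over all 12908 tested genes, the limma p-values were 0.0552 for vit-5 and 0.122 for both vit-4 and vit-3, which did not pass 0.05. The interval for vit-5 ran from -6.18 to -3.88 on the log2 scale. Its adjusted p passed without vit-5 RNAi replicate 1 (0.000558) and without vit-5 RNAi replicate 3 (0.00721), and ranged from 5.43e-08 to 0.431 over the alternatives. The sequences of vit-3, vit-4 and vit-5 are so alike that reads could have been shared or split between them, so their separate values are uncertain. Summed, the 3 genes gave 3286 ± 1137 FPKM in controls and 120 ± 96.98 after vit-5 RNAi (SD, n = 3), a 27.5-fold ratio with an exact 2-sided permutation p of 0.1.

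The other vitellogenins passed neither adjustment in the fit with group only. With molting gene level as a covariate, vit-1 (log2 fold change 0.85, adjusted p 0.00308) and vit-6 (0.92, adjusted p 0.00448) passed as higher over all genes. That covariate is a mean of genes in the same libraries and was chosen after the data were seen. For vit-2 (X, 5101032 to 5106169) the means were 2804 ± 902 and 1755 ± 740 FPKM. For vit-6 (IV, 8261157 to 8266459) they were 2704 ± 774 and 4318 ± 1666 FPKM, with 1 vit-5 RNAi library (2433 FPKM) inside the control range. For vit-1 (X, 7727889 to 7733168) they were 133 ± 85.2 and 166 ± 101 FPKM (SD, n = 3 each), and the sign of its log2 fold change, 0.20, turned negative under median-of-ratios and upper-quartile scaling, with the ribosomal RNA covariate, and without control replicate 3 (-0.13), vit-5 RNAi replicate 1 (-0.18) or vit-5 RNAi replicate 2 (-0.14). Over the list alone, vit-3, vit-4 and vit-5 passed as lower in every alternative. With vit-2 there were 4 under several alternatives, among them median-of-ratios (vit-2 log2 fold change -1.09) or upper-quartile scaling, the ribosomal RNA or molting covariate, and leaving out vit-5 RNAi replicate 1. Under some, among them either covariate, leaving out vit-5 RNAi replicate 3 and leaving out the library richest in ribosomal RNA of each group, vit-6 passed as higher over the list. All 6 genes together summed to 8927 ± 2856 FPKM in controls and 6358 ± 2465 after vit-5 RNAi (SD, n = 3), with an exact 2-sided permutation p of 0.4.

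**Figure D1:**
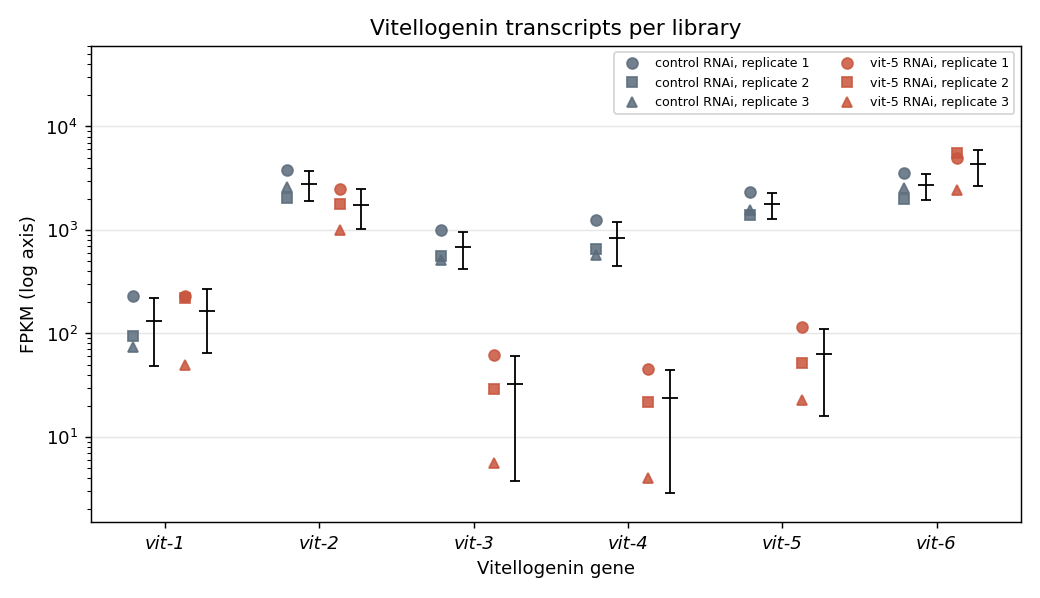
FPKM of the 6 vitellogenin genes on a log axis, with 1 symbol per library (grey for control RNAi, red for vit-5 RNAi) and bars for the mean and SD of the 3 libraries of each group. The vit-5 RNAi libraries lie below the control libraries for vit-3, vit-4 and vit-5 (22.8 to 116 FPKM against 1396 to 2335 for vit-5), and the groups overlap for vit-1, vit-2 and vit-6.

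The second question was which other transcripts differed after vit-5 RNAi. Outside the vitellogenins, the genes with the smallest p-values were higher in all 3 vit-5 RNAi libraries than in any control library, though none passed the adjusted threshold. Picking genes by p favours such separation, so it adds no support. After median-of-ratios scaling their log2 fold changes were smaller, from 0.53 (F54E2.1, 0.89 as deposited) to 1.16 (C05C12.4, 1.51 as deposited). The gene srlf-7 (gene ID 183403; IV, 7189287 to 7190333) had 207 ± 27.3 FPKM in controls and 558 ± 33.6 after vit-5 RNAi (SD, n = 3), a log2 fold change of 1.43 (SE 0.15, limma adjusted p 0.0552). The gene lgmn-1 (V, 12513059 to 12514941), which encodes legumain, an asparaginyl endopeptidase, had 70.5 ± 11.6 and 173 ± 29.4 FPKM. The lysozyme-family gene lys-10 (IV, 8332826 to 8333518) had 6.25 ± 1.24 and 19.4 ± 2.81 FPKM. For exc-5 (IV, 8799081 to 8813670), an exchange factor that shapes the excretory canal, the means were 0.98 ± 0.03 and 4.001 ± 0.21 FPKM. The remaining genes among the 10 smallest p-values were T19C9.8 (V, 17239097 to 17240721; 11.3 ± 1.64 and 29.6 ± 2.99 FPKM), C05C12.4 (IV, 11246451 to 11248081; 10.03 ± 0.69 and 30.9 ± 8.12 FPKM) and F54E2.1 (V, 2810398 to 2812017; 178 ± 18.8 and 330 ± 16.6 FPKM), all as mean ± SD with n = 3. Their limma adjusted p was 0.122, as it was for lgmn-1, lys-10 and exc-5.

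**Figure D2:**
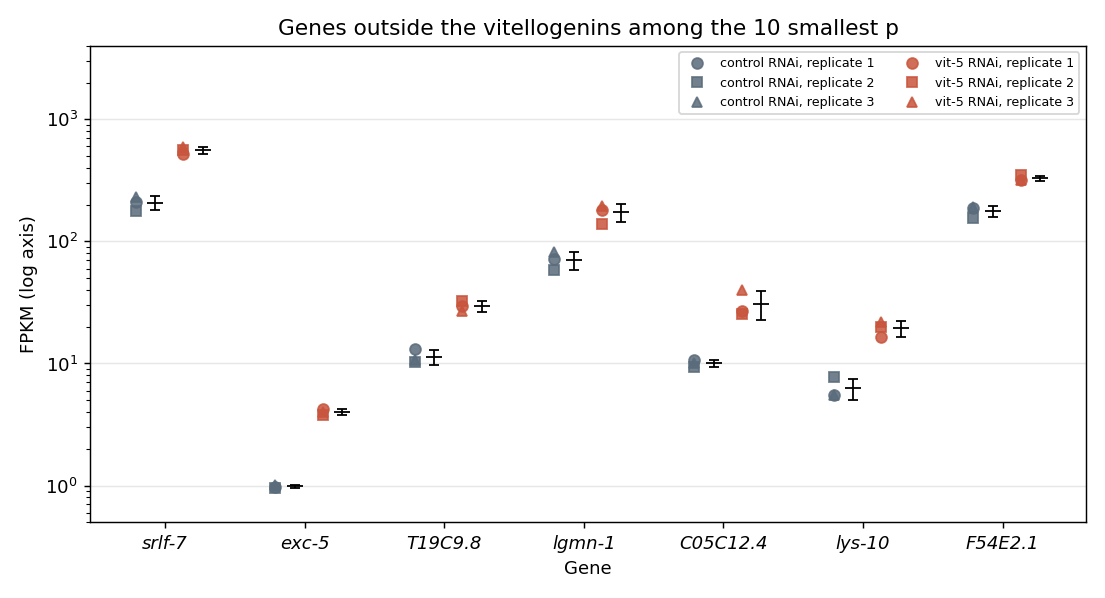
FPKM of the 7 genes other than vitellogenins among the 10 with the smallest p, on a log axis, with 1 symbol per library (grey for control RNAi, red for vit-5 RNAi) and bars for the mean and SD of the 3 libraries of each group. Each gene's vit-5 RNAi libraries lie above its control libraries, as for srlf-7 (523 to 590 FPKM against 178 to 232), which picking genes by p favours.

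Of 12908 genes tested with limma, 0 passed an adjusted p of 0.05. At an unadjusted limma p under 0.05 there were 3495 genes, 3378 higher and 117 lower after vit-5 RNAi (96.7% higher). The median log2 fold change of all tested genes was 0.34, so most genes carried a shared shift upward in FPKM. After median-of-ratios scaling, which takes that shift out, 0 genes passed and 2750 had an unadjusted limma p under 0.05, 1192 higher and 1558 lower (43.4% higher). Upper-quartile scaling gave 1634 higher and 1119 lower (59.35% higher) and quantile scaling 745 of each (50% higher), with 0 genes past the adjusted threshold in both. Without regard to size, 3982 genes had all 3 vit-5 RNAi values above all control values and 407 had them below, 34% of tested genes. The 10% given by chance is a mean over all ways of dividing the libraries, which a single division can exceed where genes move together. The share for other divisions was not computed, so the 34% is not by itself evidence for an effect of vit-5 RNAi. Leaving out vit-5 RNAi replicate 1 gave 4 genes past the adjusted threshold (vit-3, vit-4, vit-5 and the non-coding gene Y48G8AL.17), and leaving out replicate 3 gave 5 (vit-3, vit-4, vit-5, srlf-7 and the snoRNA gene C09H10.19). With molting gene level as a covariate 4262 genes passed the adjusted threshold (3955 higher, 307 lower). That covariate is a mean of genes in these same libraries and was chosen after the data were seen. Its fit kept the shared shift, with a median log2 fold change of 0.32. The numbers passing under it, here and in the lists below, are therefore not independent evidence for a change. With ribosomal RNA level as a covariate 4 genes passed, and 2 each with vitellogenin and ribosomal RNA genes out of the sum and over protein-coding genes. The number at an unadjusted limma p under 0.05 was 1471 without control replicate 2 and 1971 without control replicate 3.

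Ribosomal protein genes were lower relative to other genes. FPKM are relative values, so this fall and the shared shift upward are not independent results. Of 76 tested, 72 had a log2 fold change below 0, with a median of -0.29, or -0.63 relative to all genes. They took 30.6% ± 2.75 of the FPKM sum in controls and 26.5% ± 1.88 after vit-5 RNAi (SD, n = 3), and the exact 2-sided permutation p was 0.2. The camera test of the list against all other genes gave an adjusted p of 7.62e-40 with its preset correlation and an adjusted p of 0.702 with an estimated correlation. Adjusted over the list alone, 0 ribosomal protein genes passed on the deposited FPKM and 46 passed as lower after median-of-ratios scaling, but 0 after upper-quartile or quantile scaling. The 46 rest on the exact threshold. The 10 genes at an unadjusted limma p under 0.05 as deposited all had a list-alone limma adjusted p of 0.04999 after median-of-ratios scaling. Quantile scaling gave a median of -0.09 relative to all genes and a camera adjusted p of 0.0464. The mean for rps-4 was 4057 ± 388 FPKM in controls and 3068 ± 403 after vit-5 RNAi, and for rpl-26 it was 6717 ± 999 and 5050 ± 157 FPKM (SD, n = 3). Nuclear genes of oxidative phosphorylation, which encode subunits of the mitochondrial respiratory chain, went the same way. Of 42 tested, 37 were below 0 and the median was -0.18, or -0.52 relative to all genes (camera adjusted p 2.82e-17, and adjusted p = 0.702 with an estimated correlation). Over the list alone, 0 passed as deposited and 26 passed as lower after median-of-ratios scaling, but 0 after upper-quartile or quantile scaling. After quantile scaling the median was -0.15 relative to all genes (camera adjusted p 0.000518). The mean for cox-4, a cytochrome c oxidase subunit, was 1401 ± 227 FPKM in controls and 1053 ± 84.2 after vit-5 RNAi (SD, n = 3).

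The cuticle collagen list (131 genes) had a median of -0.13, 82 members being below 0, and the histone list (72 genes) a median of -0.07, with 44 below 0. Relative to all genes these medians were -0.47 and -0.41. The sign and size of both medians depended on which library was left out. The collagen median was -0.57 without control replicate 1, -0.44 without vit-5 RNAi replicate 3, -0.02 without vit-5 RNAi replicate 2, 0.15 without control replicate 2, 0.30 without control replicate 3 and 0.42 without vit-5 RNAi replicate 1, the last 0.07 relative to all genes. The histone median was -0.25 without control replicate 1, -0.28 without vit-5 RNAi replicate 3, -0.03 without control replicate 3, 0.07 without control replicate 2 and 0.09 without vit-5 RNAi replicate 1 or 2. With ribosomal RNA level as a covariate the medians were 0.32 and 0.11. Each list had a camera adjusted p of 3.52e-11 and an adjusted p of 0.722 with an estimated correlation, and 0 members passed over the list alone as deposited or after median-of-ratios scaling. With the molting covariate 62 collagens passed as lower and 8 as higher, and 1 histone gene as higher. That covariate was chosen after the data were seen, and its genes varied within groups together with larval collagens (median correlation 0.848). The collagen counts under it are therefore not independent evidence for a change. Cuticle collagens typical of larvae varied widely within both groups. The control libraries held 3.41, 107 and 117 FPKM of rol-6 and the vit-5 RNAi libraries 3.15, 27.8 and 202 FPKM. The adult collagen col-19 stood at 170, 171 and 80.2 FPKM in controls and 140, 162 and 30.1 FPKM after vit-5 RNAi.

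**Figure D3:**
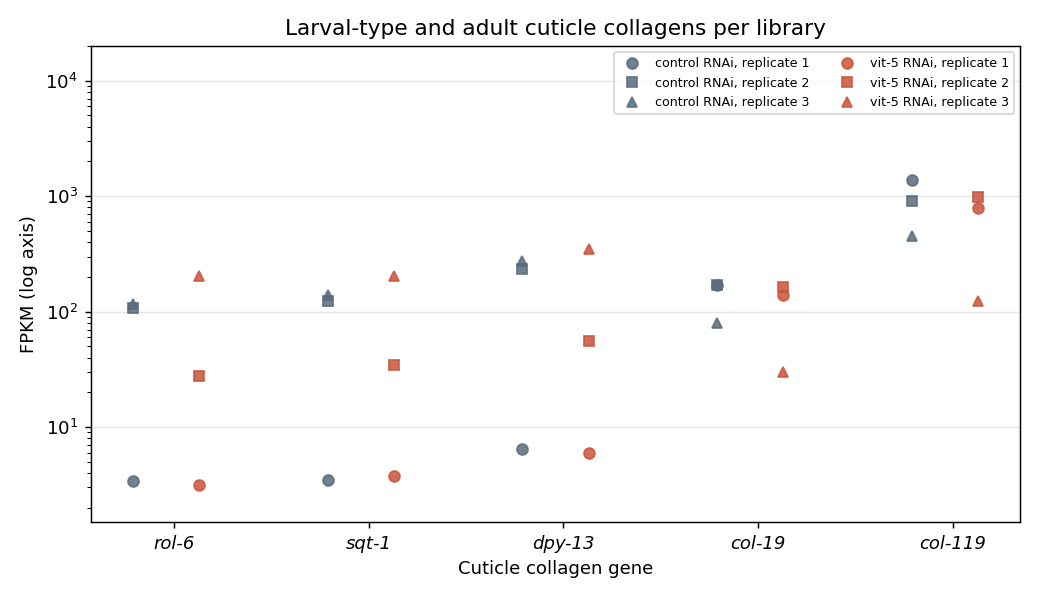
FPKM of 3 cuticle collagen genes typical of larvae (rol-6, sqt-1, dpy-13) and 2 adult ones (col-19, col-119) on a log axis, with 1 symbol per library (grey for control RNAi, red for vit-5 RNAi). The spread lies within groups, as for rol-6 (3.41 to 117 FPKM in controls and 3.15 to 202 after vit-5 RNAi).

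Lists of oocyte and germline genes (55 tested), eggshell and early embryo genes (22), oxidative stress and SKN-1 genes (29) and sperm genes (10) were lower than other genes by camera. Their adjusted p-values were 0.000177, 0.0137, 0.0377 and 0.045, and with an estimated correlation the adjusted p-values were 0.951, 0.951, 0.862 and 0.722. Median log2 fold changes were slightly above 0, at 0.01, 0.12, 0.12 and 0.04, as were the means, so these lists differed in sign from the test and lay below other genes only relative to the shared shift. After median-of-ratios scaling all 4 medians were below 0, at -0.36, -0.23, -0.23 and -0.25, and the eggshell and sperm lists were no longer called (camera adjusted p 0.104 each). The call for the oocyte list ended without vit-5 RNAi replicate 3 (camera adjusted p 0.896) and without control replicate 1 (0.124), and that for the eggshell list without the same libraries (0.797 and 0.124). The call for the oxidative stress list ended without control replicate 3 (0.061) or vit-5 RNAi replicate 2 (0.259), and that for the sperm list without control replicate 1 (0.0537), control replicate 3 (0.111), vit-5 RNAi replicate 2 (0.0625) or vit-5 RNAi replicate 3 (0.168). The sperm median was -0.04 without control replicate 1, the eggshell median -0.07 without vit-5 RNAi replicate 1 and the oxidative stress median -0.01 without vit-5 RNAi replicate 3. The oocyte median was -0.09, -0.04, -0.17 and -0.06 without control replicate 2, control replicate 3, vit-5 RNAi replicate 1 and vit-5 RNAi replicate 2. Without an expression filter the eggshell (0.166) and oxidative stress (0.178) lists were not called. Quantile scaling ended the call for the oocyte (0.1635), eggshell (0.6435) and oxidative stress (0.376) lists, and upper-quartile scaling that for the eggshell (0.086) and sperm (0.0885) lists. With molting gene level as a covariate, the oocyte (0.981), eggshell (0.6865) and sperm (0.103) lists were not called, nor were they without the library richest in ribosomal RNA of each group (0.548, 0.718 and 0.128). With ribosomal RNA level as a covariate the oxidative stress list was not called (0.0599). Only sdz-27 of the eggshell list passed over its list alone as deposited, at 29.5 ± 7.16 FPKM in controls and 58.3 ± 4.28 after vit-5 RNAi (SD, n = 3). It did not pass after median-of-ratios (adjusted p 0.0736 over the list), upper-quartile or quantile scaling, without control replicate 2 or 3 or vit-5 RNAi replicate 1 or 2, or without the library richest in ribosomal RNA of each group. With the molting covariate 18 oocyte, 7 eggshell, 4 oxidative stress genes and 1 sperm gene passed as higher over their lists, and with the ribosomal RNA covariate 4 eggshell genes passed as higher and 7 as lower.

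Genes of the intracellular pathogen response, a transcriptional program induced by microsporidia and virus, were higher relative to other genes. All 13 tested had a log2 fold change above 0, with a median of 0.74, or 0.40 relative to all genes, and 8 rose when adjusted over the list alone. Among them were drh-1, a homologue of the RNA sensor RIG-I (3.47 ± 0.33 FPKM in controls and 7.69 ± 1.15 after vit-5 RNAi), the ubiquitin ligase subunits skr-3 (50.6 ± 11.9 and 95.7 ± 29.5), skr-4 (45.4 ± 9.21 and 76.1 ± 9.48) and cul-6 (0.77 ± 0.36 and 1.75 ± 0.39), and rcs-1 (15.3 ± 1.26 and 33.7 ± 7.35; SD, n = 3 each). The remaining 3 were pals-6, pals-26 and pals-39, at means of 0.49 to 0.70 FPKM in controls and 1.46 to 2.72 FPKM after vit-5 RNAi. The expression filter admitted these 3 and cul-6 through their vit-5 RNAi values. Without that filter 36 genes of the list were tested and the median was 0.30 (0.14 relative to all genes). Then 7 passed as higher, of which only 4 (drh-1, pals-6, rcs-1 and skr-4) were among the 8. Only drh-1, pals-6 and rcs-1 passed over the list alone after median-of-ratios or upper-quartile scaling and without control replicate 1 or 2. There were 5 without vit-5 RNAi replicate 3 and 0 after quantile scaling. The camera adjusted p was 0.0115, with an adjusted p of 0.722 with an estimated correlation, and it was 0.0701 without control replicate 1, 0.0602 with the molting covariate and 0.058 without the library richest in ribosomal RNA of each group.

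Intestinal marker genes were also higher relative to other genes. Of 27 tested, 25 were above 0 with a median of 0.51, or 0.16 relative to all genes, and 10 rose when adjusted over the list alone. These were the intermediate filament genes ifp-1 and ifd-2, the filament organizer ifo-1 (4.51 ± 0.71 FPKM in controls and 9.95 ± 1.63 after vit-5 RNAi), the metallothionein mtl-1 (358 ± 111.6 and 752 ± 171), the gut esterase ges-1 (12.5 ± 3.18 and 26.2 ± 5.67), the desaturase fat-2 (361 ± 49.3 and 539 ± 65.3; SD, n = 3 each), nhx-2, itr-1, erm-1 and eps-8. None of the 10 passed over the list alone after median-of-ratios, upper-quartile or quantile scaling, or without control replicate 2, control replicate 3 or vit-5 RNAi replicate 1, and 6 passed without vit-5 RNAi replicate 2. The camera adjusted p was 0.0377 (adjusted p = 0.951 with an estimated correlation), and it was 0.155 after median-of-ratios scaling, 0.124 after upper-quartile scaling, 0.101 without vit-5 RNAi replicate 2, 0.063 with the ribosomal RNA covariate and 0.0731 without the library richest in ribosomal RNA of each group. In that last alternative 0 members passed over the list alone, and with the molting covariate 16 did.

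**Figure D4:**
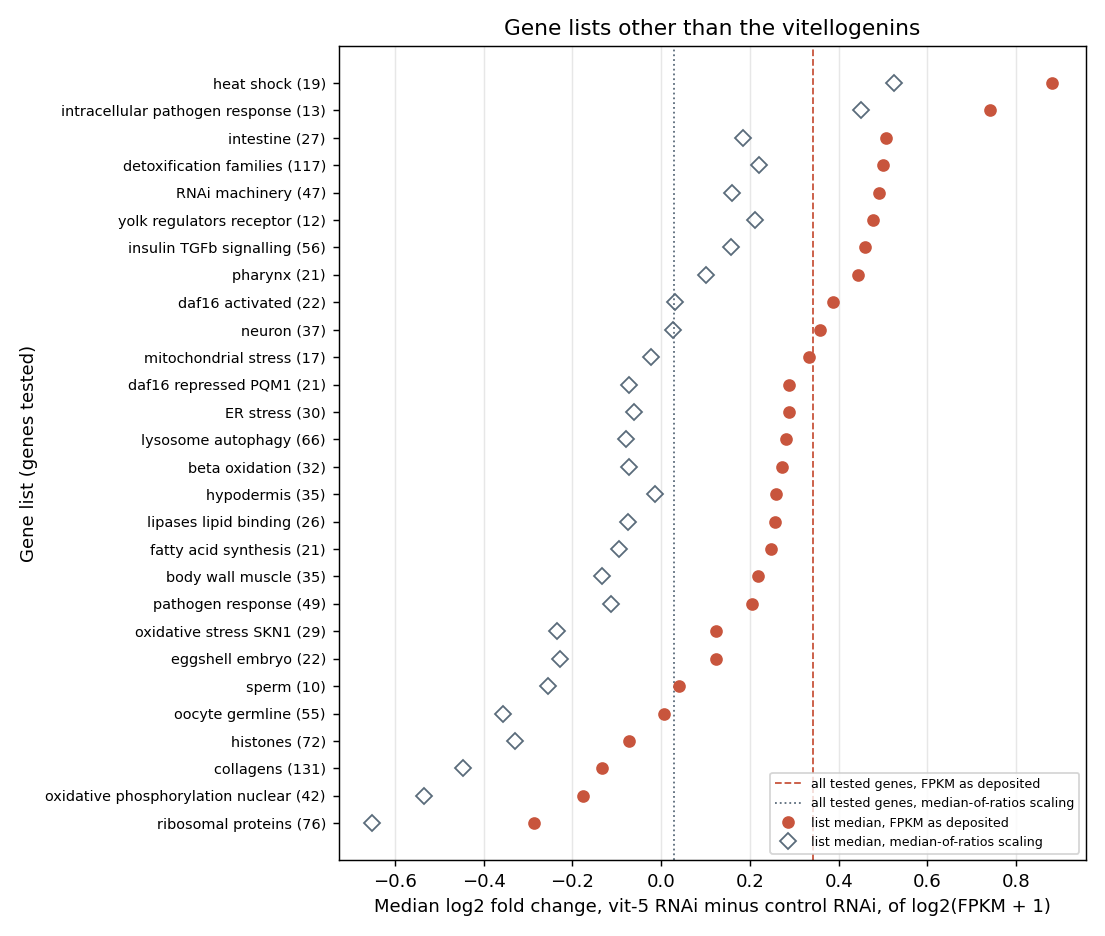
Median log2 fold change (vit-5 RNAi minus control RNAi, of log2(FPKM + 1)) of 28 gene lists, all those tested except the vitellogenins. The number of genes tested is in parentheses. Filled circles are from deposited FPKM and open diamonds from values after median-of-ratios scaling. Vertical lines mark the median of all tested genes, 0.34 as deposited and 0.03 after scaling, and ribosomal proteins (-0.29) and oxidative phosphorylation (-0.18) lie lowest.

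The other 18 lists were not called by camera as deposited (adjusted p 0.0794 to 0.901), though some were under alternatives named below. In these lists the members that rose over the list alone lost that call after median-of-ratios scaling unless named otherwise. None of their members passed over all genes as deposited. At an unadjusted limma p under 0.05, 3378 of all 12908 tested genes were higher, so a rise alone does not set a member apart. In each of the 18 lists 0 members passed as higher over the list alone without control replicate 2. Without the library richest in ribosomal RNA of each group only dod-23 did, in the list of genes repressed by DAF-16. With the molting covariate 2 to 44 members of each of the 18 lists passed as higher over the list alone, and with the ribosomal RNA covariate 0 to 19. Of 26 lipase and lipid-binding genes, 5 rose, the lipase genes lipl-2 (gene ID 185840, which carries the name lipl-3 in the deposited files, the RefSeq name being used here; 6.89 ± 2.102 FPKM in controls and 26.2 ± 9.32 after vit-5 RNAi; SD, n = 3), lipl-3 and lipl-7 and the lipid-binding protein genes lbp-5 and lbp-7. This count was 0 without vit-5 RNAi replicate 1, 1 without control replicate 3 or vit-5 RNAi replicate 2, 9 without vit-5 RNAi replicate 3 and 0 without an expression filter. Of 32 genes of beta-oxidation, 2 rose as deposited and after median-of-ratios or upper-quartile scaling, the acyl-CoA oxidase acox-3 (10.7 ± 3.18 and 28.2 ± 5.77 FPKM) and the enoyl-CoA hydratase family gene ech-8 (3.19 ± 0.95 and 7.73 ± 1.17 FPKM; SD, n = 3), and 3 others passed as lower after median-of-ratios scaling. The 2 became 0 without control replicate 3, vit-5 RNAi replicate 1 or vit-5 RNAi replicate 3, 6 without control replicate 1, and 0 after quantile scaling or without an expression filter. Fatty acid synthesis (21 genes, median 0.25) had 0 members past the list-alone threshold as deposited, 5 with the molting covariate and 3 with the ribosomal RNA covariate (fat-2, fat-6 and nhr-49). The regulators of yolk synthesis and uptake (12 genes) had 2 that rose, pqm-1 (33.9 ± 5.67 and 57.2 ± 8.16 FPKM) and ceh-20 (14.4 ± 0.19 and 25.9 ± 3.77 FPKM; SD, n = 3), both for transcription factors. That count was 0 also without control replicate 1, control replicate 3, vit-5 RNAi replicate 1 or vit-5 RNAi replicate 2. In the lysosome and autophagy list (66 genes) nuc-1, a lysosomal DNase, rose from 122 ± 23.9 to 227 ± 18.6 FPKM (SD, n = 3). It did not pass without control replicate 3, vit-5 RNAi replicate 1 or vit-5 RNAi replicate 2, with a pseudocount of 0.1 or without an expression filter, and 2 genes of the list passed without vit-5 RNAi replicate 3. Camera called this list (adjusted p 0.000518) and the lipase list (0.00152) higher after quantile scaling, and the lipase list without an expression filter (0.04997).

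Among stress and immunity lists, 4 of 30 endoplasmic reticulum stress genes rose over the list alone, namely the stress sensors pek-1 (4.57 ± 0.90 and 10.8 ± 2.74 FPKM) and atf-6, the chaperone calnexin cnx-1 (46.5 ± 7.03 and 78.0 ± 10.3 FPKM; SD, n = 3) and T14G8.3. None passed without control replicate 2, control replicate 3, vit-5 RNAi replicate 1 or vit-5 RNAi replicate 3, or without an expression filter. Of 49 pathogen response genes, 3 rose, spp-5 (3274 ± 265 and 5232 ± 286 FPKM; SD, n = 3), C17H12.8 and irg-2. This was 0 without control replicate 2 or vit-5 RNAi replicate 2, 1 without control replicate 1, 6 without control replicate 3, 2 without vit-5 RNAi replicate 3 and 0 without an expression filter. Genes repressed by DAF-16 (21 tested) had 3 that rose, cdr-2, dod-23 and ges-1, which became 0 without control replicate 2, vit-5 RNAi replicate 1 or vit-5 RNAi replicate 2 and 1 without control replicate 3. Genes activated by DAF-16 (22) had 0, and 2 without control replicate 1 or vit-5 RNAi replicate 3. Heat shock genes (19) had the highest list median, 0.88, but 0 passed as deposited, and their median FPKM ranged from 35.9 to 118 within the control libraries alone. Without vit-5 RNAi replicate 2, 10 of them passed, and the median was 0.41 without control replicate 2 and 0.56 without vit-5 RNAi replicate 3, with camera's direction then downward, as without vit-5 RNAi replicate 1 (median 0.80). Camera called this list higher after quantile scaling (adjusted p 0.018), while without the library richest in ribosomal RNA of each group its median was 0.07 and the direction downward. Detoxification families (117 genes, median 0.50) and the insulin and TGF-beta list (56, median 0.46) had 0 past the list-alone threshold as deposited. With the molting covariate 44 detoxification genes passed as higher and 4 as lower, and 19 insulin and TGF-beta genes as higher and 4 as lower. With the ribosomal RNA covariate 19 and 7 passed as higher, and 1 detoxification gene did without control replicate 1. Mitochondrial stress genes (17, median 0.33) had 0 as deposited and 2 without vit-5 RNAi replicate 3, while after median-of-ratios scaling 1 passed as higher and 3 as lower. Genes of the RNAi machinery (47, median 0.49) had 0 that passed, 17 without vit-5 RNAi replicate 3 and 31 with the molting covariate. With 1 library left out, camera called the RNAi list higher (adjusted p 0.0274 without control replicate 1, 0.000971 without vit-5 RNAi replicate 3), the detoxification list higher (0.0409, 0.0342 and 0.0217 without control replicate 2, vit-5 RNAi replicate 1 and vit-5 RNAi replicate 2) and the pathogen list lower (0.0156 without vit-5 RNAi replicate 3). The detoxification list was also called higher after median-of-ratios (0.0294) or upper-quartile scaling (0.0492) and without an expression filter (0.01175). The RNAi list was also called higher without that filter (0.0394), with the molting covariate (0.000562) and without the library richest in ribosomal RNA of each group (0.00423). In the last 2 of these alternatives the pathogen list was called lower (0.0197 and 0.0147), and after quantile scaling the list activated by DAF-16 was called higher (0.0319).

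Of the tissue lists, 4 of 37 neuronal genes rose over the list alone, unc-13 and rab-3 of synaptic vesicle release (rab-3 at 7.69 ± 1.46 and 17.95 ± 4.38 FPKM), ric-4 and aex-3. None passed without control replicate 2, control replicate 3, vit-5 RNAi replicate 2 or vit-5 RNAi replicate 3, or without an expression filter, and the list median of 0.36 was 0.04 without vit-5 RNAi replicate 3. Of 21 pharyngeal genes, 3 rose, the myosin myo-5 (1.33 ± 0.30 and 3.69 ± 0.29 FPKM) and the troponin tnt-4 (17.5 ± 4.12 and 40.3 ± 6.25 FPKM; SD, n = 3), which passed also after median-of-ratios scaling, and pha-4. The count was 0 without control replicate 2 or vit-5 RNAi replicate 2, 1 without control replicate 3, 6 without vit-5 RNAi replicate 1 and 0 after quantile scaling. Body wall muscle (35 genes, median 0.22) and hypodermis (35, median 0.26) had 0 that passed as deposited, and without vit-5 RNAi replicate 3 their medians were 0.00 and 0.02 and camera called both lower (adjusted p 0.0143 and 0.016). Camera called the neuronal list higher without vit-5 RNAi replicate 1 (adjusted p 0.0134) and the pharyngeal list higher without that library (0.00177) or control replicate 3 (0.0433). With the ribosomal RNA covariate both were called higher (0.0467 and 0.01925), 11 neuronal and 6 pharyngeal genes passing over their lists. Camera called body wall muscle and hypodermis lower with the molting covariate (0.00781 and 0.00599), and body wall muscle lower without the library richest in ribosomal RNA of each group (0.02735). There the neuronal and body wall muscle medians were both -0.02. The median FPKM of the neuronal (26.33), body wall muscle (181.3), pharyngeal (19.84) and hypodermal (27.31) lists was highest in vit-5 RNAi replicate 3, the library with the most rol-6 (202 FPKM), the highest mean log2 of molting genes (5.092) and the most ribosomal RNA (3.46% of the FPKM sum). With the shared shift removed by median-of-ratios scaling, the medians of 10 of the 18 lists turned negative, namely lysosome and autophagy, lipases and lipid binding, beta-oxidation, fatty acid synthesis, pathogen response, hypodermis, body wall muscle, endoplasmic reticulum stress, genes repressed by DAF-16 and mitochondrial stress.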

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

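Scaling, covariate, gene type and ribosomal RNA alternatives were chosen after the data were seen. The planned count-based alternatives (other count normalizations, count filters, a second count test and voom) were not run because the files hold no counts. The number of genes past the adjusted limma threshold, 0, stayed at 0 with a pseudocount of 0.1, without a filter, without the library richest in ribosomal RNA of each group, and under median-of-ratios, upper-quartile and quantile scaling. It became 2 (1 higher, 1 lower) with vitellogenin and ribosomal RNA genes taken out of the sum, 2 (1 higher, 1 lower) over protein-coding genes, 4 (1 higher, 3 lower) with ribosomal RNA level as a covariate and 4262 (3955 higher, 307 lower) with molting gene level as a covariate. With the replicate number as a block it became 3806 (3679 higher, 127 lower), vit-2 (adjusted p 0.032) among them. Over the lists alone, 4 vitellogenins then passed as lower and vit-6 as higher. As higher there also passed 51 detoxification, 21 insulin and TGF-beta, 12 heat shock and 7 fatty acid synthesis genes. Most other lists had members that passed as higher too, among them 24 RNAi machinery, 16 lysosome and autophagy, 16 intestinal, 15 pathogen response and 14 neuronal genes. None did in the ribosomal protein, oxidative phosphorylation, collagen, histone, sperm and hypodermis lists. A few lists also had members that passed as lower. The heat shock list was called by camera (adjusted p 0.0197). The deviations of same-numbered libraries from their group means correlated at 0.753, 0.0339 and 0.681, and 4 of 6 libraries correlated best with their own number, a hint from the data that is not part of the design. Leaving out 1 library gave 0 to 5 genes (0 to 1 higher, 0 to 4 lower). For vit-5 the log2 fold change was -5.03 with the block, -4.98 with those genes out of the sum, -5.37 with the ribosomal RNA covariate, -4.57 with the molting covariate and -5.03 over protein-coding genes, each then past the threshold, and -5.61 to -4.46 with 1 library left out. Fewer genes were adjusted for in the protein-coding set, and for the other changes the cause was not tested. The 11 lists called became 0 with an estimated correlation and stayed within 8 to 14 in the other alternatives. The vit-1 log2 fold change, 0.20 and not past the threshold, was 0.85 (past it, adjusted p 0.00308) with the molting covariate, -0.161, -0.083 and -0.191 under median-of-ratios scaling, upper-quartile scaling and the ribosomal RNA covariate, and -0.18 to 0.92 with 1 library left out. The median of the oocyte list relative to all genes was -0.52 to -0.072 with 1 library left out, and its camera direction turned at -0.072, without vit-5 RNAi replicate 3. The rough depths, and values without counts, leave the precision of genes near 1 FPKM unknown.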

Other observations

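The tests on larval collagens, on the ratio of vitellogenin paralogs and on sums outside the 100 most abundant genes, and the scaling settings, were chosen after those results were seen, while the tests on the share of those 100 genes, on lysosomal hydrolases and on other splits of the libraries were set before theirs. Within the lysosome and autophagy list, 25 autophagy genes had a median log2 fold change of 0.36 (0.02 relative to all genes), 20 proton pump genes 0.18 (-0.16 relative to all genes) and 17 cathepsin-type and other hydrolases 0.25 (-0.09 relative to all genes). The camera adjusted p-values over these 3 lists were 0.142, 0.813 and 0.813. The lysosomal proteins lgmn-1 and nuc-1 prompted the question whether lysosomal hydrolases as a set were higher than other genes, and camera gave an adjusted p of 0.8132 over the 17, with the test's direction upward and the median below that of all genes by less than the spread of the members. A median below that of all genes was the bound set in advance against the hypothesis, and it was too weak for members that spread this widely, so the hypothesis stays open.

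Cuticle collagens typical of larvae differed strongly between libraries of the same group. Besides rol-6, sqt-1 ranged from 3.50 to 205 FPKM and dpy-13 from 5.92 to 350 FPKM over the 6 libraries, and both were low in control replicate 1 and vit-5 RNAi replicate 1 and highest in vit-5 RNAi replicate 3. The first component of all tested genes held 45.5% of the variance and the second 40.5%. In the first, the libraries low in these collagens lie at -35.0, -41.6 and -14.2 (vit-5 RNAi replicate 2), and the others at 15.9 to 48.8. The second separated the groups, with controls at 16.85 to 45.58 and vit-5 RNAi libraries at -43.12 to -14.4. Components were computed on deposited FPKM without scaling between libraries. The median-of-ratios factors also separated the groups, at 0.7796 to 0.9728 in controls and 1.097 to 1.17 after vit-5 RNAi. The second component can therefore carry the shared shift upward and is not separate support for an effect of vit-5 RNAi.

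Scaling of whole libraries is excluded for this collagen pattern, since the ratio of rol-6 to the adult collagen col-19 ranged 333.5-fold, and dilution by ribosomal RNA is excluded because it took at most 3.465% of the FPKM sum. RNAi against vit-5 does not account for it either, because control libraries alone spanned 3.41 to 117 FPKM of rol-6 (exact 2-sided permutation p = 0.9 between groups). Larval material, or animals at another stage, may be present in some libraries. As that hypothesis needs, 23 molting and seam cell genes deviated from their group means together with the larval collagens, their median correlation of 0.848 lying at percentile 100 of 10000 random lists matched on expression. Adult epidermis may express some of the 23 genes too, and the random lists were not matched on joint variation. The percentile therefore cannot tell larval material from other variation of the epidermis. Whether worms were separated from their offspring is not given in the sources used here.

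Most genes at an unadjusted p under 0.05 were higher after vit-5 RNAi. Scaling could be the source, since after median-of-ratios scaling 43.35% of such genes were higher, but that scaling centres the genes by construction and cannot decide. A lower share of the 100 most abundant genes is excluded as the whole source. With libraries rescaled to equal sums outside them, the median log2 fold change of the other tested genes was 0.2968 (0.344 as deposited). It was 0.138 to 0.451 over the 9 pairs of a vit-5 RNAi and a control library, which share libraries. Only this cut-off of 100 genes was tried, so a lower share of a wider set of abundant genes stays open. The 100 genes took 40.98% ± 3.30 of the sum in controls and 36.3% ± 2.02 after vit-5 RNAi (SD, n = 3), a difference of -4.67 percentage points, and the groups overlapped, which with 3 libraries a side leaves a part of the shift open to it. A global rise caused by vit-5 RNAi was not tested and stays open, because FPKM carry no absolute amount.

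The fall of vit-3 and vit-4 beside vit-5 could reflect silencing of all 3 similar transcripts, or reads of 1 gene shared among them. The ratio of vit-3 plus vit-4 to vit-5 was 0.84 ± 0.14 in controls and 0.78 ± 0.31 after vit-5 RNAi (SD, n = 3; exact 2-sided permutation p = 0.9), which either explanation allows, so they cannot be told apart without the reads.

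With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 0 genes past the adjusted threshold, and the highest other split gave 99 in one direction and 30 in the other. That split set control replicate 1 and vit-5 RNAi replicates 1 and 2 against the other libraries, the division seen in the larval collagens. This points to a structure of the samples beside the treatment. The second component separated the treatment groups on deposited FPKM, where it can also carry the shared shift upward. At an unadjusted limma p under 0.05 the real split gave 3495 genes and the highest other, the same division, 3118. For gene lists the real split called 11 and the highest other 15, and 8 of the 10 splits, the real one included, called at least 11.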
